A study of Xenopus tropicalis with 8 samples.

How the data were processed

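Total RNA from Xenopus tropicalis embryos was measured on 8 single-colour (Cy3) Agilent oligonucleotide arrays, 4 from control embryos and 4 from embryos exposed to 887 ppm of Disperse Yellow 7 (DY7). The group and the replicate number of each sample came from its title and treatment label. Per the file headers, the arrays lay on 2 slides of 4, and each slide carried control and DY7 samples of the same 2 replicate numbers.

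The deposited scanner files hold intensity values on a linear scale, 1 per spot, which were made with Agilent Feature Extraction, version 10.7.3.1 on slide 1 and version 10.7.1.1 on slide 2, per the file headers. The processed intensity was corrected for background and spatial trend within each array by that software, per the file headers, and was not yet scaled between arrays. The deposited series matrix holds log2 values for the same spots, and each of its columns correlated at 0.986 or higher with the log2 processed intensity of the same array. The column medians of that log2 matrix, as deposited by the authors, ran from 5.10 in control 1 to 5.27 in control 2 (DY7 arrays 5.17 to 5.19, control 3 5.16, control 4 5.12). Its scale and direction followed from this match, and the method of its centring between arrays is not given in the sources used here.

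Each array held 45220 spots, of which 1417 were controls and were left out. The rest belonged to 32899 distinct probes, and replicate spots of a probe were averaged on the log2 scale after spots carrying an outlier flag were removed. No spot was saturated. The main values were log2 processed intensity minus the 75th percentile of the array. A probe was kept where it lay well above background on all 4 arrays of at least 1 group. This kept 20321 probes, and 32 of them were left out because an outlier flag had emptied an array, so that 20289 were tested.

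The arrays carry transcript accessions without gene names. Accessions were matched without their version numbers to a RefSeq gene table of assembly UCB_Xtro_10.0, used for names only. The array design was built on JGI 4.1, per the file headers of slide 2, and no coordinates are given. The match named 5891 of the 32899 probes (17.9%), which stand for 5617 genes, 4639 of them with a gene symbol. Nearly all curated transcript accessions matched (745 of 769), while 5143 of 14476 predicted ones and 3 of 17654 others did. Unmatched probes were tested but remain unnamed here. The design names 15119 probes as cross-hybridising and 17780 as specific, and a gene read by a cross-hybridising probe is marked as such in the text.

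Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with version 1.17.8 of the data.table package. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, over 20289 probes or, separately, over 3436 genes, each represented by its brightest probe. In all, 42 gene lists of 1948 symbols were fixed in advance, and 270 of their genes were measured. The 29 lists with 5 or more measured members were tested with camera at a preset correlation between genes of 0.01. They were tested again with an estimated correlation and with fry. The mean of each list per array was compared by an exact two-sided permutation test over the 70 assignments of 8 arrays, whose smallest possible p is 0.0286. In limma's fits the standard error (SE) refers to the difference between group means of 4 arrays each.

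Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. That rule took the 12 largest rises and the 12 largest falls among called genes with a symbol whose 4 DY7 arrays all lay on one side of the 4 control arrays, plus up to 4 members with the smallest p in each list past its threshold and in 8 lists reported whatever their result (xenobiotic metabolism, conjugation, oxidative stress, heat shock, p53, cell cycle, globins and thyroid hormone). It named 52 genes, 2 of which are not reported here. A further 39 genes, up to 4 called members of each other list and all called members of a wider endoplasmic reticulum list, were chosen after their values were seen.

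The scripts were tested on simulated data made from the means and spreads of the real probes. Among the 20289 probes of the DY7 comparison, 200 simulated changes were recovered for 47.8% of probes at 1.5-fold, 74.6% at 2-fold and 98.5% at 3-fold; 3.92% of the calls were false, and no call was made when nothing was changed. For the gene lists, over 3436 genes, a list of 13 genes raised by 0.5 on the log2 scale was called, and none of the other lists was. The simulated noise was drawn independently for each probe and array. These rates therefore do not cover correlation between genes, array effects or pairing.

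The replicate numbers were checked for pairing through the deviations of arrays from their group means. The correlations between control and DY7 arrays of the same number were 0.306, 0.107, 0.455 and 0.449 for numbers 1 to 4. All were over 0.1, so the numbers were treated as pairing the samples in alternative fits. Arrays of different numbers ranged from -0.389 to 0.305, a range that holds the value of number 2. The main fits, camera, fry and the exact permutation test did not use the pairs, so their p-values do not account for them. The labels do not say what a shared number stands for; same-numbered arrays also shared a slide. The blocked counts stand beside the others where they differ by over 1.5 times.

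Alternatives covered background correction, scaling between arrays, the filter on dim probes, slide, replicate number, variance model, the deposited log2 table, thresholds, the probe that represents a gene, and leaving out each array in turn. Normexp correction (offset 50) had been planned on mean spot signals; the scanner files used here have median signals, which took their place. Alternatives added after seeing the data were specific probes alone, quantile normalization together with leaving out control 2, fry with the replicate block, and normexp after each local background above 3 times the array median was set to that median, on all arrays, on control 3 alone or on the other 7 alone. The slide as a random block was run for probes and genes, and not for lists.

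The number of arrays, 4 per group, limits the precision. The labels do not say whether replicates came from separate clutches or tanks, so p-values measure the spread between these samples, part of which may be technical.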

Results

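Disperse Yellow 7 (DY7) is an azo dye used on synthetic textiles. The study asked how exposure to it during development alters gene expression in embryos of the western clawed frog, with 4 control samples and 4 samples exposed to 887 ppm; the labels give embryonic stages 12 to 46 and no vehicle. The signal at the 75th percentile of the probes ran from 162 to 327 on the control arrays and from 126 to 202 on the DY7 arrays. Probes well above background made up 70%, 51.6%, 73.2% and 75.9% of all probes on control arrays 1 to 4, and 64.0%, 64.7%, 72.5% and 73.5% on DY7 arrays 1 to 4. Over the tested probes, arrays correlated at 0.972 to 0.995 within the controls, 0.98 to 0.993 within DY7 and 0.955 to 0.987 between groups. Within DY7, arrays 2 and 3 (0.993) and arrays 1 and 4 (0.991) were the most alike. DY7 4 correlated more closely with control 4 (0.987) than with DY7 2 (0.98) or DY7 3 (0.985).

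DY7 embryos had higher transcript levels of several endoplasmic reticulum chaperones and of a sterol synthesis enzyme, and lower levels of cd36l, of a mitochondrial uncoupling protein and of the immediate early transcription factor junb. Among called genes with a symbol and no overlap between the groups, the largest rise was that of serpinh1, a collagen chaperone. The log2 fold change of serpinh1 was 1.75 ± 0.22 (SE, n = 4 arrays per group, limma adjusted p = 0.00209). Next among specific probes came xa-1 (1.75 ± 0.22) and hspa5, the main Hsp70-type chaperone of the endoplasmic reticulum (1.40 ± 0.14, adjusted p = 0.000919). The largest fall among the same genes was that of cd36l, at -2.40 ± 0.18 (adjusted p = 0.000232), or 5.27-fold. Changed probes without a gene name were not ranked. The crystallin gene cryga.1 (-2.13 ± 0.25) and the carbonic anhydrase gene ca1 (-2.10 ± 0.37) were also called lower, but lay near background in DY7, so the sizes of their falls are uncertain.

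Other rises on specific probes came from sqle, the squalene epoxidase of sterol synthesis (1.28 ± 0.15), ckb, the brain-type creatine kinase (1.22 ± 0.15), fabp6, a bile acid binding protein of the gut (1.2 ± 0.17), prdm15 (1.25 ± 0.35) and msmb.1 (1.14 ± 0.16). Of the rises, serpinh1, sqle, prdm15 and msmb.1 lay well above background on 3 of 4 control arrays. The same held for the called rises of hspa1b, jund, stard4, tuba1a, ppara, rbp2, vcan, pde6c, pkm and atp7b given below. The prdm15 call was lost with quantile normalization and with the repaired normexp correction described below. Cross-hybridising probes gave rises for h4c3, a core histone (1.57), or5f1l1.2, an olfactory receptor (1.5), and nek2, a mitotic kinase (1.14 ± 0.11). The probes of h4c3 and or5f1l1.2 ran close together on every array (-2.78 and -2.69 on control 4, 0.22 and 0.04 on DY7 2). Whether they read separate transcripts was not tested, so they may not be separate rises. The other falls on specific probes were those of ucp3, a mitochondrial uncoupling protein (-1.94 ± 0.25), junb, an immediate early transcription factor (-1.58 ± 0.16), cryga.7 (-1.47 ± 0.34), ch25h, a cholesterol hydroxylase (-1.43 ± 0.20), arsa.2, an arylsulfatase (-1.28 ± 0.21), smarca1, a chromatin remodelling ATPase (-1.15 ± 0.11), and ppdpfl (-1.14 ± 0.12). A second ch25h probe read -0.66 with an adjusted p of 0.0670 over probes. Cross-hybridising probes gave falls for cttnbp2 (-2.02 ± 0.21) and fosl1, a partner of the Jun proteins (-1.58 ± 0.21). In DY7, cryga.1 was well above background on 1 of 4 arrays and ca1 on 2 of 4, and both were so on all 4 control arrays. With the repaired normexp correction both falls shrank, to -0.40 and -0.48, and were not called. The genes fosl1 (-0.21) and ch25h (-0.27), each above background on 3 of 4 DY7 arrays, were not called either. This correction also adds an offset of 50, against median signals of 31 to 72 on the arrays. Such an offset shrinks the fold changes of dim probes by itself, and its part was not separated from that of the background. On the same correction ucp3, also above background on 3 of 4, kept its call at -0.59, serpinh1 kept it at 0.98 and hspa5 at 1.24, so that serpinh1 no longer led hspa5.

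**Figure D1:**
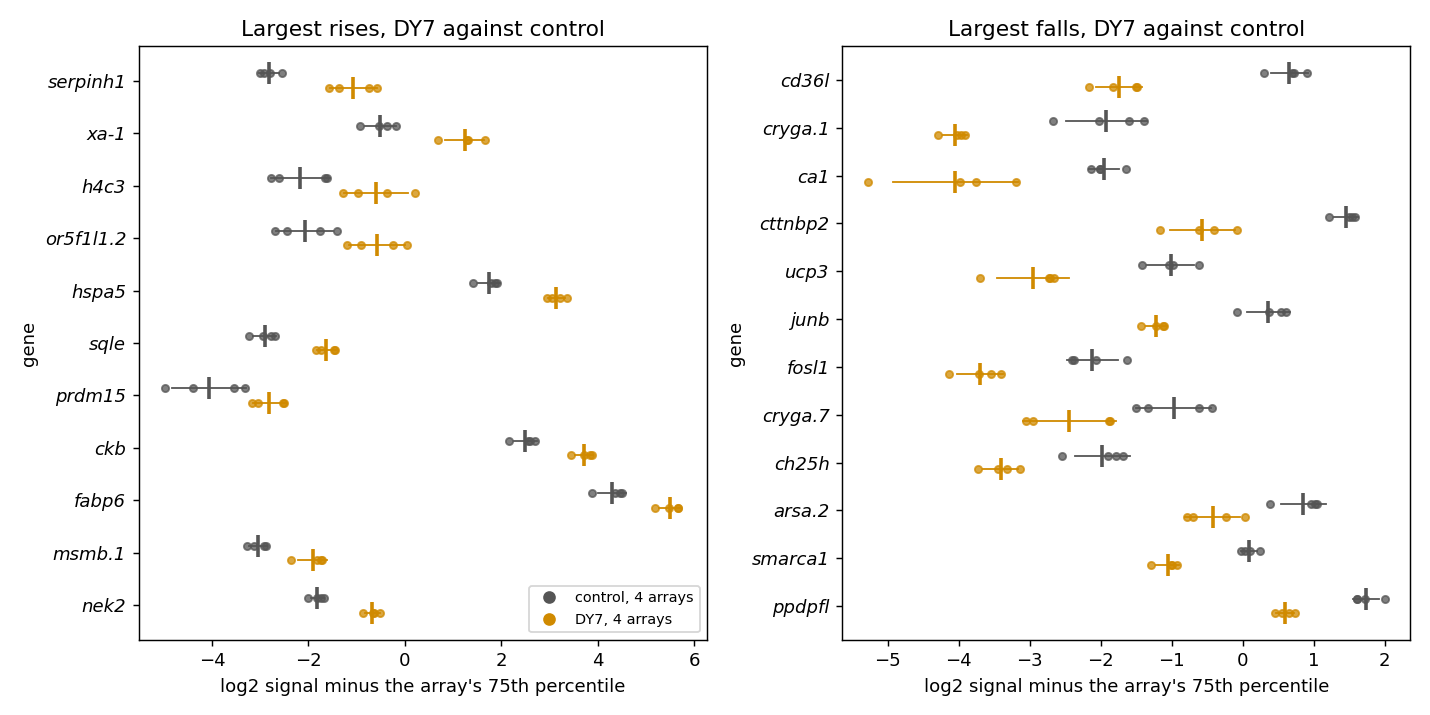
Log2 signal minus the 75th percentile of the array (x axis) for 11 of the 12 genes with the largest rises (left) and the 12 with the largest falls (right); points are arrays, 4 per group, ticks are group means and lines are 1 SD to each side. The 4 DY7 arrays lie on one side of the 4 control arrays for each gene shown, as the selection required.

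In total, 2867 of 20289 probes differed between the groups (1839 higher and 1028 lower in DY7), and 498 of 3436 named genes did (316 higher and 182 lower). Changes of at least 2-fold were seen for 252 probes that rose and 89 that fell. The 4 arrays of one group lay apart from those of the other for 21.6% of probes, where the average over all 70 assignments of the arrays is 2.86%. Probes share array effects, so a single assignment may lie far from that average, and the contrast is no test of chance. Of the changed probes, 2360 matched no reference gene. With the replicate number as a block, 5124 probes (3247 higher, 1877 lower) and 851 genes (538 higher, 313 lower) changed; with the slide as a block the counts were 2741 and 470. Within slide 1 alone, 2 arrays against 2, 6 probes and 6 genes passed, and 3450 probes had an unadjusted p under 0.05; within slide 2 it was 0 probes, 13 genes and 3308 probes.

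The direction of the changes depended on the scaling. Of the changed probes 64.1% were higher, against 54.3% with quantile normalization (1968 higher, 1656 lower), 43.8% with scaling to the median (1035 and 1330), 4.73% without scaling (34 and 685) and 52.4% without control 2 (1742 and 1581), the array with the fewest probes above background. The median log2 fold change of all tested probes was 0.06 in the main analysis, -0.06 with scaling to the median and -0.42 without scaling. The planned normexp background correction left 14 probes and 7 genes. Once extreme local backgrounds of single spots had been set to the array median, a repair made after the data were seen, 1454 probes and 235 genes passed; repairing control 3 alone gave 1545 and 263, and repairing the other 7 arrays alone gave 13 and 7. Without control 1, DY7 2, DY7 3 or control 4, 1147, 1091, 1191 and 1094 probes and 213, 213, 216 and 211 genes passed. Of the 24 genes with the largest changes, 19 kept their call whichever array was left out; among the rest, h4c3, or5f1l1.2 and prdm15 lost it without control 1, DY7 2, DY7 3 or control 4 (prdm15 also without DY7 1), and cryga.7 without DY7 1, DY7 2 or control 4. With the repaired normexp correction, 41 of the 74 called genes chosen for naming kept their call and 33 lost it. Rises that lost it were those of prdm15, smc4, epor, nop2, psmc1, psmb7, tuba1a, pold1, rfc3, cpt1a, ppargc1a and ppara. Others were vcan, pax3, gucy2d, pde6c, apob, pkm, atp7b, uggt2, txndc12 and mesd. Falls that lost it were those of cryga.1, ca1, fosl1, ch25h, cyp2c19, adh7, ier2, crhbp, c1r and egln2. Of the 74 genes, 42 kept their call whichever array was left out. Among genes named below, top2a, rbp2 and nefl lost it without control 1, DY7 2, DY7 3 or control 4, atp7b also without control 2, and vcan also without DY7 1. The genes smc4, tuba1a and pde6c lost it without any 1 array other than control 3 or DY7 4, and epor, crhbp and c1r without any 1 other than control 2 or DY7 4. The same held for gucy2d other than control 2 or control 3, rfc3 other than control 2, and egln2 other than control 3. Calls were lost for nop2 without control 1 or DY7 1, wdr43 without these, DY7 2 or control 4, psmb7 without DY7 2 or control 4, apob without these or DY7 3, and krt78.6 without control 4.

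No gene list passed camera's threshold, so the lists below are described by their members. Of 29 lists tested 0 had an adjusted p under 0.05, 9 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0507, for the immediate early genes. With an estimated correlation the smallest adjusted p was 0.574. In fry, which asks whether the members of a list move on balance one way and does not compare them with other genes, 13 lists passed, 10 upward and 3 downward. With the replicate number as a block, camera again called 0 lists and fry 10. By camera, 2 lists passed without control 1, 4 without DY7 1, and 1, the immediate early genes, without DY7 2 or control 4.

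Calls among chaperones came mainly from genes of the endoplasmic reticulum. In the heat shock and protein folding list, 4 of 9 measured members rose and none fell (4 adjusted over the list alone): serpinh1, hspa5, hsp90b1, the Hsp90 of the endoplasmic reticulum (1.06 ± 0.13), and the cytosolic Hsp70 gene hspa1b (0.53 ± 0.15, adjusted p = 0.0394), whose call was lost with quantile normalization, with median scaling and without any 1 array other than DY7 1. The list mean rose from 0.16 ± 0.12 to 0.63 ± 0.09 (SD, n = 4, exact permutation p = 0.0286), and the camera adjusted p was 0.248 (0.574 with an estimated correlation, 0.0119 in fry). In the unfolded protein and amino acid stress list 2 of 5 rose (3 adjusted over the list alone), namely the disulfide isomerase gene pdia4 (0.96 ± 0.11) and creld2 (1.08 ± 0.13); camera gave an adjusted p of 0.146 (0.574 with an estimated correlation) and fry 0.00324. The mean shift of that list was 0.58 within slide 1 and 0.41 within slide 2.

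Sterol synthesis and ribosome assembly genes moved upward. Of 9 measured cholesterol and sterol genes, 3 rose and none fell (4 adjusted over the list alone): sqle, sc5d, which acts late in cholesterol synthesis (0.96 ± 0.13), and the sterol carrier gene stard4 (0.76 ± 0.19), the last of which lost its call without control 1, control 2, DY7 2, DY7 3 or control 4. Of 6 ribosome biogenesis genes, 4 rose and none fell: emg1 (0.70 ± 0.10), mphosph10 (0.75 ± 0.13), nop2 (0.53 ± 0.12) and wdr43 (0.67 ± 0.17). Camera's adjusted p was 0.0730 for the sterol list and 0.0733 for the ribosome biogenesis list (both 0.574 with an estimated correlation), and fry's was 0.0119 and 0.00498. Of 5 proteasome genes, 2 rose, psmc1 (0.53 ± 0.11) and psmb7 (0.45 ± 0.11). The camera adjusted p of that list was 0.113 (0.574 with an estimated correlation) and that of fry 0.0170. With scaling to the median nop2, wdr43, psmc1 and psmb7 lost their calls. Of 2 ribosomal protein genes measured, rps19 rose on a cross-hybridising probe (0.68 ± 0.12).

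Among cell cycle genes, 4 of 13 rose and none fell: nek2 and kif20a, a mitotic kinesin (0.76 ± 0.15), on cross-hybridising probes, and top2a, a topoisomerase (0.80 ± 0.20), and smc4, a condensin subunit (0.42 ± 0.12), on specific ones. With the replicate number as a block 7 were higher and 1 lower. Adjusted over the list alone, 4 were higher and 1 lower, and camera's adjusted p was 0.0863 (0.574 with an estimated correlation; 0.0259 in fry). The mean of the list lay between -0.67 and -0.62 on control arrays 1, 3 and 4, at -0.96 on control 2 and between -0.40 and -0.36 on the DY7 arrays. The smc4 call was lost with quantile normalization, with median scaling and with the slide as a block. Of 8 DNA replication genes, 2 rose (4 adjusted over the list alone, and 4 with the replicate block), the polymerase gene pold1 on a cross-hybridising probe (0.49 ± 0.10) and the clamp loader gene rfc3 (0.39 ± 0.11). Both lost the call with median scaling. The camera adjusted p of the list was 0.371 (0.574 with an estimated correlation, 0.0258 in fry).

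Immediate early genes, which respond within minutes to stimuli, were lower in DY7 for 4 of 8 members: junb, fosl1, ier2 on a cross-hybridising probe (-0.80 ± 0.15) and per1 (-0.48 ± 0.09). One, jund, was higher on a cross-hybridising probe (0.85 ± 0.17). The list mean fell from -0.69 ± 0.11 to -1.15 ± 0.03 (SD, n = 4, exact permutation p = 0.0286), by similar amounts within slide 1 (-0.45) and slide 2 (-0.48), and the adjusted p was 0.0507 by camera, 0.574 with an estimated correlation and 0.00324 in fry. With the repaired normexp correction fosl1 and ier2 lost their calls.

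Genes of foreign compound metabolism were called in both directions. In the list of aryl hydrocarbon receptor and phase I genes, 1 of 7 rose, maob, a monoamine oxidase (0.92 ± 0.12), and 2 fell, cyp2c19 (-0.83 ± 0.14) and the alcohol dehydrogenase gene adh7 (-0.60 ± 0.11), both of which lost their calls with the repaired normexp correction. The receptor target cyp1b1, read by a cross-hybridising probe, stood at -0.34 ± 0.10 with an adjusted p of 0.0533 and passed with the replicate number as a block. That probe was very bright, with a control mean of 6.94 against 6.35 for apob, and which transcripts it reads was not tested. None of 3 conjugation and transport genes was called, with log2 fold changes of -0.20 for abcg2, 0.00 for gstz1 (cross-hybridising) and -0.01 for abcc4. The fixed lists held 50 phase I, 51 conjugation and 48 oxidative stress symbols, so most of their members were not measured here. Of 4 oxidative stress genes, me1, the malic enzyme, rose (0.78 ± 0.14), and hmox1 (-0.16), gpx1 (-0.08) and nfe2l1 (0.10), the last 2 on cross-hybridising probes, gave no call. None of 9 p53 and DNA damage genes was called, among them xrcc5 (0.64 ± 0.20, adjusted p = 0.0578), cdkn1a (-0.25, cross-hybridising) and msh6 (0.26). For this list the fry adjusted p was 0.0448 and camera's 0.662 (0.744 with an estimated correlation). Camera's adjusted p for the phase I list was 0.376.

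Lipid and energy genes were split. Of 14 fatty acid and PPAR genes 3 rose, cpt1a, the mitochondrial carnitine transferase (0.72 ± 0.19), the coactivator ppargc1a (0.65 ± 0.18) and the receptor ppara (0.96 ± 0.28), and 1 fell, ucp3 (2 with the replicate block). The median member stood at -0.18, and camera's adjusted p was 0.376. None of the 3 rises was called without control 1, control 2, DY7 2, DY7 3 or control 4, and 3 members were lower without control 2. With the slide as a block ppargc1a and ppara lost their calls. On DY7 4 all 3 stood near their level on control 3 (cpt1a 0.479 and 0.455, ppargc1a -1.912 and -1.895, ppara -2.411 and -2.426). Of 4 glycolysis and hypoxia genes pkm rose on a cross-hybridising probe (0.67 ± 0.12) and egln2 fell (-0.36 ± 0.11, not called with median scaling), and of 2 iron and copper genes atp7b, a copper transporter, rose (0.90 ± 0.25, not called with the slide as a block). None of 4 electron transport genes (1 higher adjusted over the list alone, and 1 with the replicate block) and none of 4 steroid synthesis genes was called.

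**Figure D2:**
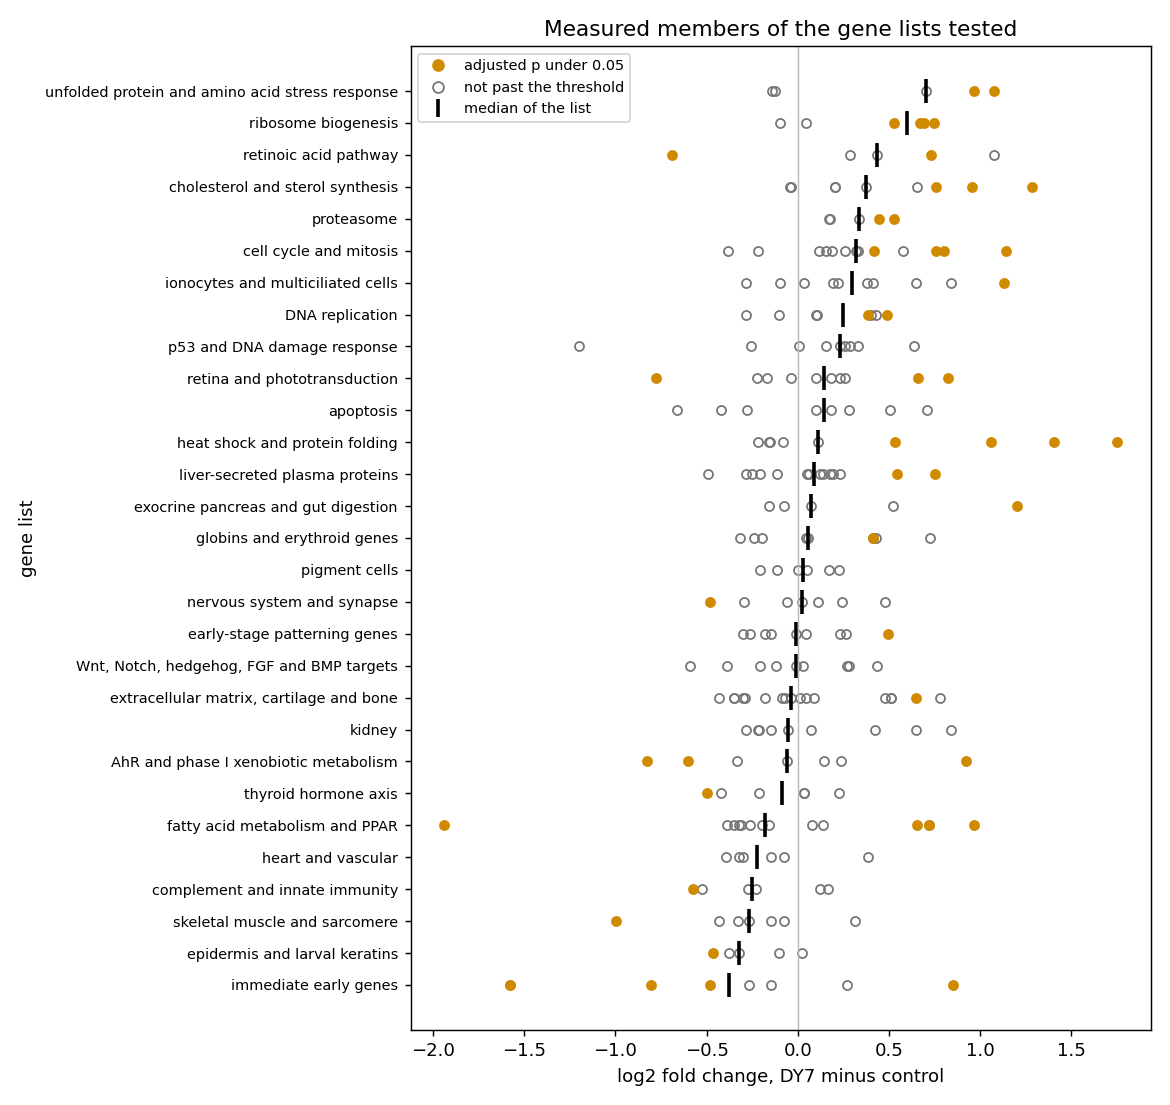
Log2 fold change, DY7 minus control (x axis), of each measured member of the 29 gene lists tested; filled points passed an adjusted p of 0.05 over all genes, open points did not, and ticks are list medians. Medians run from -0.37 for the immediate early genes to 0.71 for the unfolded protein list, and no list as a whole passed camera's threshold.

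Tissue markers gave scattered calls. In skeletal muscle 1 of 7 genes fell, the slow troponin gene tnnt1 (-1.0 ± 0.11), with a camera adjusted p of 0.0733 (0.574 with an estimated correlation) and 0.00498 in fry. In epidermis 1 of 5 fell (3 adjusted over the list alone, and 3 with the replicate block), krt78.6 on a cross-hybridising probe (-0.47 ± 0.10). The camera adjusted p of that list was 0.0733 (0.574 with an estimated correlation), and that of fry 0.0448. Of 10 retina genes, 2 rose, gucy2d (0.66 ± 0.18) and pde6c (0.83 ± 0.24), and 1 fell, rom1 (-0.78 ± 0.16); gucy2d and pde6c lost their calls with the replicate block and with quantile normalization. Of 14 liver plasma protein genes, 2 rose, serpina1 (0.75 ± 0.12) and apob (0.55 ± 0.13). The apob call was lost with median scaling. In the exocrine pancreas and gut list fabp6 rose and 4 members gave no call (2 higher with the replicate block). Its adjusted p was 0.586 by camera, 0.699 with an estimated correlation and 0.0259 in fry. In the ionocyte and multiciliated cell list tuba1a rose on a cross-hybridising probe (1.13 ± 0.33), but not with the slide as a block or random block. The other 9 members gave no call, and none passed adjusted over the list alone (4 higher with the replicate block). The adjusted p of this list was 0.332 by camera, 0.574 with an estimated correlation and 0.0495 in fry.

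In the erythroid list 1 of 9 rose, the erythropoietin receptor gene epor (0.41 ± 0.11), and 4 did so adjusted over the list alone (2 with the replicate block). The genes slc4a1 (0.41), slc25a37 (0.73, cross-hybridising) and fech (0.43) did not pass over all genes. The epor call was lost with median scaling and with the slide as a block. In the thyroid hormone list 1 of 6 fell, crhbp, which binds corticotropin-releasing hormone (-0.50 ± 0.14), and foxe1 (-0.42), pax8 (-0.21) and nkx2-1 (0.23), all 3 on cross-hybridising probes, were not called. One member each was called among 6 complement genes (c1r, -0.58 ± 0.16), 7 neural genes (nefl, -0.48 ± 0.12), 17 matrix, cartilage and bone genes (vcan, 0.65 ± 0.16, cross-hybridising), 9 early-stage patterning genes (pax3, 0.49 ± 0.10, cross-hybridising) and 4 clock genes (per1, with 2 lower adjusted over the list alone). The pax3 call was lost with median scaling and with the repaired normexp correction. The retinoic acid list had 1 rise, rbp2 (0.73 ± 0.18), and 1 fall, rarg (-0.69 ± 0.11, cross-hybridising), among 5; adjusted over the list alone 4 were higher and 1 lower. With the replicate block the counts were 0 for complement, 3 higher and 3 lower for matrix, cartilage and bone, 1 and 1 for early-stage patterning, 1 and 1 for the clock, and 2 and 1 for retinoic acid. Median and mean differ in sign for the matrix (-0.04 and 0.06), kidney (-0.05 and 0.12), lens (-0.05 and 0.11) and early-stage (-0.01 and 0.02) lists. None was called among 8 apoptosis, 9 kidney, 6 heart and vascular, 6 pigment cell, 9 signalling target, 4 lens, 4 leukocyte, 3 protease and hatching, 1 endocrine and 1 housekeeping genes. With the replicate block 2 apoptosis and 2 signalling target genes were lower, 1 kidney, 1 lens and 1 leukocyte gene were higher, and of the heart and vascular genes 1 was higher and 2 were lower. The fixed lens list did not hold cryga.1 or cryga.7.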

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

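Each measure below has 1 array whose gap to its nearest neighbour was large against the range of its group of 4 (Dixon's test at 1 in 20), on the scale of log2 signal minus the 75th percentile. Such a gap was seen in 19 of 244 groups tested, where chance gives about 12, and no explanation was tested for any of them.

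Control 2 stood apart in 8 of the 19. It was highest for abcc4 (-1.41, nearest control -2.91), nefl (4.31, nearest 4.00) and the mean of the p53 and DNA damage list (-0.29, nearest -0.83). It was lowest for c1r (-1.16, nearest -0.72), kif20a (-2.63, nearest -2.12), rom1 (0.59, nearest 1.09), the apoptosis list (-1.94, nearest -1.57) and the cell cycle list (-0.96, nearest -0.67).

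Control 3 stood apart in 6. It was lowest for arsa.2 (0.39, nearest 0.97) and pax8 (1.1, nearest 1.26), and highest for atp7b (-3.03, nearest -3.76), smc4 (-1.72, nearest -2.01), the retinoic acid list (-0.039, nearest -0.22) and the unfolded protein list (0.69, nearest 0.55).

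Among DY7 arrays, DY7 1 was lowest for ucp3 (-3.70, nearest -2.73) and highest for the early-stage patterning list (1.11, nearest 0.99). DY7 2 was highest for rfc3 (1.79, nearest 1.52), DY7 3 for txndc12 (0.54, nearest 0.05) and DY7 4 for uggt2 (-0.038, nearest -0.25).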

How the results depend on the processing

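The values for specific probes, fry with the replicate block, the 3 forms of normexp after background repair, and quantile normalization without control 2 were chosen after seeing the data; the others were planned. Planned normexp gave 14 probes, 7 genes and 3 lists: on control 3 the local background of 28 spots lay above 3 times the median of 39 (highest 19084), and the fitted noise SD was 352, against 0.908 to 3.62 on all arrays after such backgrounds were set to the median, when 1454 probes, 235 genes and 0 lists passed. With control 3 alone repaired 1545, 263 and 0 passed, and with the other 7 arrays alone repaired 13, 7 and 3. Of the 1454 probes, 1349 were among the 2867 of the main analysis; the cause of the rest of the loss was not tested. Without scaling 719 probes, 116 genes and 1 list passed, and without the filter, over more probes, 562, 142 and 1. The replicate block raised the counts to 5124 probes and 851 genes and changed no list call by camera; array weights gave 7135 and 1227, with weights from 0.323 for control 2 to 4.59 for control 4. With 2 arrays per group, slide 1 gave 6 probes and 6 genes, and slide 2 gave 0 probes (3308 at an unadjusted p under 0.05), 13 genes and 3 lists. An adjusted p under 0.1 gave 5067 and 826, a fold of at least 1.5 gave 1488 and 285, and specific probes alone gave 1454 probes, of 10255 tested, and 3 lists. For lists, fry gave 13, and 10 with the replicate block. Leaving out 1 array gave 1091 to 3323 probes, 211 to 579 genes and 0 to 4 lists. Counts of probes and genes stayed within 1.5 times the main ones with quantile normalization, median scaling, the deposited log2 table, the slide as a block or random block, the stricter filter and a trended variance. Without scaling the signs of smc4 (-0.055), epor (-0.062), psmb7 (-0.026), rfc3 (-0.086), uggt2 (-0.064) and mesd (-0.093) turned and their calls ended, where the median of all probes moved to -0.42. Over all alternatives named genes lost a call 634 times with their sign kept, besides those 6, and gained one 27 times.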

Other observations

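The tests of the share of higher probes and of the endoplasmic reticulum genes were chosen after the result was seen; those of splits, of developmental stage and of the probes kept without control 2 were written before their results, control 2 being named because its low share of probes above background had been seen. Beyond the 5 endoplasmic reticulum genes of the report, a wider list of folding and export genes of that compartment was written before their values were looked up, and 10 further members were measured. Of these, 3 rose and none fell: uggt2, a glycoprotein folding sensor (0.41 ± 0.10), txndc12 on a cross-hybridising probe (0.53 ± 0.14) and mesd, a receptor chaperone (0.38 ± 0.10). Each lost its call with median scaling and in at least 6 of the 8 fits that left out 1 array. The genes edem3 (0.86) and uggt1 (0.74) did not pass.

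Whether chance can be excluded was asked with the 35 splits of the 8 arrays into 4 and 4. For the probes, 1 of the 35 splits, the real one, gave as many calls (2867, highest other 0, with up to 3917 at an unadjusted p under 0.05 there). For the genes it was again 1 (498, highest other 0, up to 768). Both shares lie under 0.05, but these splits ignore the replicate pairs. Splits that mix the groups also carry any group difference as spread, which lowers their calls. Among the 8 splits that part all 4 replicate pairs the others also gave 0 probes and 0 genes, but 8 are too few for a share under 0.05. With the pairs kept, chance is therefore not excluded. The split by slide gave 0 probes with 750 at an unadjusted p under 0.05. For the gene lists, 35 of 35 splits gave as many (highest other 3), which a real count of 0 makes certain, so that the splits say nothing about the lists. Without control 2, the array with 51.6% of probes above background, 86.4% of the called probes were still called in the same direction, which argues against that array as the source of the calls as a whole.

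The first pattern is the surplus of higher over lower probes, 64.1% of the calls, or 72.2% on cross-hybridising and 56.1% on specific probes. Without control 2 the share was 52.4%, and with any other array left out it stayed above 64%; with quantile normalization it was 54.3%, and the median log2 fold change of the dimmest 4058 probes went from 0.23 to 0.08, and to 0.13 without control 2. With both together the share was 46.8%. Quantile normalization centres all probes near 0 (median 0.00), so its shares decide neither for the scaling nor against an excess of raised transcripts in DY7 embryos. Without control 2 the higher calls went from 1839 to 1742 and the lower ones from 1028 to 1581. The share thus fell mainly through falls not called with that array. The filter on dim probes may also bear on the share, because it kept probes above background in either group alone. Among the 16694 probes above background on all 8 arrays, 58.6% of the calls were higher (1856 higher, 1310 lower). The median log2 fold change there was 0.018, against 0.058 in the main analysis. This stricter filter also drops dim probes as such, so the selection was not separated from low signal. What lies behind the higher calls and the remaining shift of dim probes stays open.

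The second pattern is the rise of hspa5, hsp90b1, serpinh1, pdia4 and creld2, by 1.25 on average. All 5 kept their calls without control 2, where the smallest log2 fold change was 0.92, and with quantile normalization, where it was 0.94. The values argue against control 2 and against the scaling as the source of the rise. Control 2 had the fewest probes above background, but the signal at the 75th percentile was lower on DY7 2 (126 against 162). The median of all 9 members of the fixed heat shock list was 0.109 (spread 0.49), below the smallest rise of the 5 (0.96) by more than that spread. The 5 were singled out after their values were seen, and some of them belong to that list. This gap is therefore partly built in and decides nothing about a rise of all chaperones alike. The other 6 members of the list had a mean log2 fold change of 0.005, with hspa1b among them called higher (0.53). They are what was left once hspa5, hsp90b1 and serpinh1 had been taken out for their values. The mean of all 9 members rose by 0.47, so the value of the 6 decides nothing either. Whether the rise spans the folding genes of the compartment stays open: the 10 other members of the wider list had a median of 0.25 and a camera p of 0.0754 (0.195 with an estimated correlation). The planned normexp fit, set by spots of control 3, kept the call of hspa5 and lost those of serpinh1 (0.68), creld2 (0.77), hsp90b1 (1.00) and pdia4 (0.98), the last 2 with folds near those of the main analysis; the repaired one kept all 5, and without scaling serpinh1 alone kept its call.

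The third pattern is the set of gene lists that moved on balance one way, which a younger stage of the DY7 embryos might produce. Such a lag would raise patterning, cell cycle and DNA replication genes and lower markers of muscle, lens, retina, pancreas and liver. The cell cycle list had a median of 0.32 (camera p 0.018, adjusted 0.0863) and the muscle list -0.27 (camera p 0.011, adjusted 0.0733). Both met the unadjusted camera p under 0.05 that had been set beforehand for a lag. The DNA replication list (0.25, camera p 0.18) did not. The lens list stood at -0.05 (mean 0.11), and the retina (0.14), pancreas (0.07) and liver (0.09) lists had medians above 0 without passing. Outside the lens list, the crystallin genes cryga.1 (-2.13) and cryga.7 (-1.47) fell, the direction of a lag. They were not part of the prediction and were named for the size of their falls. In DY7, cryga.1 lay near background. A patterning median at or below 0 had been set beforehand as evidence against a lag. It was -0.011, which meets that bound, but by far less than the spread of its 9 members (0.36). The spread was not part of the bound. A stage difference cannot be told apart from other sources here, because the patterning members go both ways and the labels give 1 range of stages for all samples.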
